A study of Mus musculus with 12 samples.

How the data were processed

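RNA from the hippocampus was sequenced in 12 libraries, 3 for each of 7-month saline, 7-month nicotine, 18-month saline and 18-month nicotine mice. The deposited tables hold raw fragment counts per gene, 1 table per age, with no normalization by the authors. Per the submitters' processing notes reads were aligned with TopHat (version not stated) to GRCm38; the counting tool, the gene annotation and the strand setting are not stated, so that sense and antisense reads cannot be told apart. The protocol text in the labels describes a small RNA library kit, while the counts cover mRNA and noncoding genes. The tables have 44788 (7 months) and 44786 (18 months) genes, of which 44760 have the same name in both and were joined for the fits that hold both ages. A transcript length was found for 32195 of these.

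Depth per library is the sum of its counts, 25071195 to 29245972 at 7 months and 21260068 to 23715015 at 18 months. Statements on depth cover counting error alone. Groups came from the labels. Replicate numbers were tested as a block and not used as pairs, since departures of same-number libraries from their group means had correlations across genes from -0.24 to 0.178 (3 per comparison). Even so, both 7-month libraries numbered 3 had more Rn18s-rs5, Rn7sk and Lars2 than the other 7-month libraries.

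Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, genes kept by filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment at 0.05). Nicotine was compared with saline within each age from the 6 libraries of that age. The nicotine effect averaged over both ages, its difference between ages, and age within each infusion came from fits of 4 group means to all 12 libraries. CPM are scaled by the TMM factors, except those of single libraries for Ttr, Gh, Malat1, Rn18s-rs5, Rn7sk and Lars2 at the start of the results, which are scaled by total counts alone. Exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.1, so single genes were tested by the model alone.

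Before the data were examined, 41 lists of genes (895 entries) were fixed for pathways, cell types and other tissue that a hippocampal dissection could hold. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each was also tested with an estimated correlation and with fry. The lists, comparisons, alternatives and the rule for named genes were set at the same time. That rule took the 10 largest changes each way among genes that passed, had a symbol that is not a predicted name, had groups that do not overlap and a mean log2 CPM of at least 1. With fewer than 10 genes passing it took the 10 with the smallest p. It added up to 4 smallest-p members of each list described, and App, Chrna7, Chrna4, Chrnb2, Gfap, Trem2, Cst7, Arc and Fos in every comparison. A few genes that the rule takes are not reported here. The values of Ttr, Gh, Malat1, Rn18s-rs5, Rn7sk and Lars2 in single libraries were chosen after they were seen. Concordance of the nicotine effects between ages was measured by Pearson and Spearman correlation across genes and by the share of same-direction genes, against 100 relabellings of drug within age.

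Alternatives fixed in advance were RLE size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, replicate number as a block, 1 library left out at a time, all 12 libraries in 1 fit for the within-age comparisons, and leaving out both first 7-month libraries, whose descriptions have another prefix. Offsets from a regression of each library on transcript length and GC content (splines with 4 degrees of freedom), fits of the same genes without these offsets, and fits without libraries that stood apart, were added after the data were seen. An alternative for normalized values was not run, as the tables hold counts. Transcripts of genes called at 18 months were compared with those of other tested genes with BLAST 2.17.0, at 95% identity or more over 200 nt or more. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

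The procedure was tested on simulated data with 200 changed genes per comparison. At a 2-fold change it recovered 38% (nicotine, 7 months), 74% (nicotine, 18 months), 84% (average), 46% (difference), 64% (age, saline) and 62% (age, nicotine) of the changed genes; at 4-fold 88%, 94%, 94%, 66%, 92% and 84%. The share of false calls was 5.83%, 9.83%, 6.51%, 9.76%, 2.82% and 2.26%. A simulated list shifted by -0.7 on the log2 scale was called by camera, with an estimated correlation and by fry, and 0 of 40 other lists were called by camera or by fry. Each gene was simulated independently of the others, so the simulation could not test the preset inter-gene correlation. Some gene symbols in the tables were changed into dates before deposit and were left as they stand.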

Results

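RNA from the hippocampus of male APP/PS1 mice was sequenced after a 14-day infusion of nicotine hydrogen tartrate or saline from a pump under the skin. APP/PS1 mice carry transgenes that include mutant human amyloid precursor protein and deposit amyloid plaques with age. The 12 libraries fell into 4 groups of 3, formed by age (7 or 18 months) and infusion. Replicate libraries were taken to be separate animals only as far as the labels say. The dose is labelled 48 mg/kg/h, a unit that was taken over as labelled. Total counts ranged from 25071195 to 29245972 per library at 7 months and from 21260068 to 23715015 at 18 months. Mean values are in CPM, the usual unit of counts scaled to a common library size, with the SD over n = 3 libraries, and log2 fold changes are given with a standard error (SE). The SE was taken as the absolute log2 fold change divided by the square root of the F statistic, so it restates the F-test. Coordinates are on GRCm38, the build named in the labels.

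The first principal component, with 80.3% of the variance of log2 CPM over 10890 genes, separated the ages. 7-month saline library 2 lay between them, at 7.16 on that axis, while the other 7-month libraries lay between -43.1 and -36.8 and the 18-month libraries between 30.2 and 32.9. Transcripts over 5000 nt took 32.0% of the counts of that library, 22.9% to 23.8% in the other 7-month libraries and 35.8% to 36.6% at 18 months. Malat1, a nuclear long noncoding RNA, had 374 CPM in 7-month saline library 2, 273 to 373 CPM in the rest of the 7-month libraries and 5071 to 6326 CPM at 18 months. Transthyretin (Ttr), a choroid plexus product, reached 5855 CPM in 7-month nicotine library 1, which also held 89.3 CPM of growth hormone (Gh), a pituitary transcript that stayed under 1.5 CPM in the other libraries. Ttr had 1482 CPM in 7-month saline library 3 and 38.0 to 395 CPM in the remaining 7-month libraries. At 18 months Ttr was highest in nicotine library 1, with 1390 CPM, and was 65.2 CPM or lower in the other 18-month libraries. Saline library 3 and nicotine library 3 at 7 months held 17602 and 8110 CPM of Rn18s-rs5, where the other 7-month libraries had 455 to 690 and the 18-month libraries 22224 to 27437. They also held 61.0 and 35.7 CPM of Rn7sk (1.36 to 2.18 in the other 7-month libraries, 156 to 251 at 18 months) and 3938 and 1684 CPM of Lars2 (101 to 144, and 5159 to 6356).

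**Figure D1:**
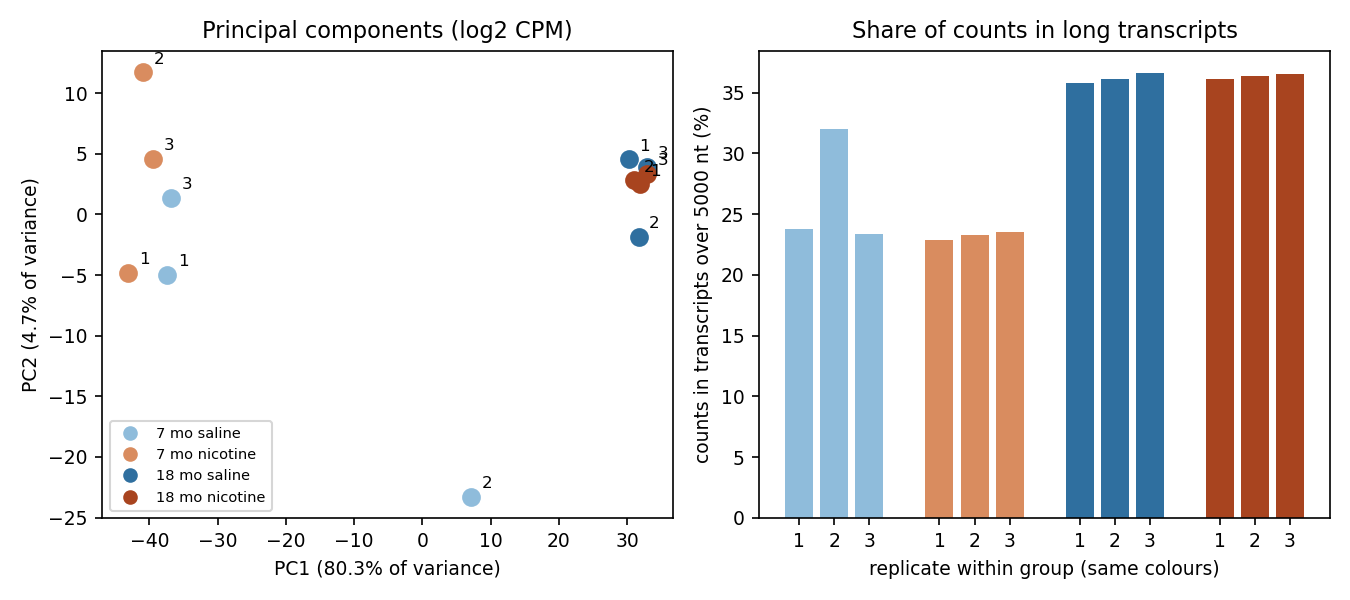
The left panel plots each library on the first 2 principal components of log2 CPM, coloured by group and numbered by replicate; the right panel plots the percent of each library's counts in transcripts over 5000 nt. 7-month saline library 2 stands apart from the other 7-month libraries, with 32.0% of its counts in long transcripts.

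The first comparison asked how nicotine changed hippocampal expression at the earlier stage of disease. In 7-month mice Plin4, which codes for a lipid droplet coat protein, had 6.68 ± 0.388 CPM under saline and 52.8 ± 12.3 CPM under nicotine (log2 fold change 2.98, SE 0.18, adjusted p = 0.0064). Egr2, an activity-induced transcription factor, had 9.47 ± 2.0 CPM under saline and 1.03 ± 0.239 CPM under nicotine (log2 fold change -3.19, SE 0.26, adjusted p = 0.0245). Plin4 lies on chromosome 17 at 56100587 to 56109948 and Egr2 on chromosome 10 at 67534469 to 67542188. Genes induced by neuronal activity were lower as a list, and 27 of the 30 measured members had a negative fold change (adjusted p = 5.6e-16, and adjusted p = 0.0707 with an estimated correlation). Genes that respond to glucocorticoids were higher as a list, with 11 of the 17 measured members above 0 (adjusted p = 0.00273, and adjusted p = 0.770 with an estimated correlation).

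Among the immediate early genes, 1 of 30 passed over all genes tested, Egr2, while 17 were lower and 1 was higher when adjusted over the list alone. Their median log2 fold change was -0.66. Egr1 had 193 ± 19.9 CPM under saline and 75.3 ± 13.1 CPM under nicotine, with adjusted p = 0.119. Fos had 33.1 ± 1.29 and 9.94 ± 2.66 CPM, with adjusted p = 0.119. Arc, which codes for a synaptic plasticity protein, had 293 ± 34.6 and 131 ± 33.2 CPM, with adjusted p = 0.600. In each of these genes the 3 nicotine libraries lay below the 3 saline libraries. They were named for their small p, and groups did not overlap in 17.4% of all genes tested at 7 months, where chance gives 10%.

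Of the 17 measured glucocorticoid-response genes, 1 passed over all genes, Plin4, and 7 were higher and 1 lower when adjusted over the list alone. Hif3a had 5.05 ± 1.17 CPM under saline and 19.6 ± 6.44 CPM under nicotine (adjusted p = 0.341). Fkbp5, a regulator of the glucocorticoid receptor, had 61.8 ± 6.86 and 116 ± 36.7 CPM (adjusted p = 0.656). The circadian list was lower (4 of 17 members above 0; adjusted p = 0.0279, and adjusted p = 0.770 with an estimated correlation), and it included Per2 at log2 fold change -0.75 (SE 0.14) and Per1 at -0.45 (SE 0.10), neither of which passed. The circadian call was lost without saline library 1 (adjusted p = 0.132), saline library 3 (0.0519), nicotine library 2 (0.0680) or nicotine library 3 (0.0507).

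Ribosomal protein genes had a median log2 fold change of 0.27, and all 78 members lay above 0 (adjusted p = 2.6e-14, and adjusted p = 0.770 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.23, with 65 of 66 members above 0 (adjusted p = 2.8e-12, and adjusted p = 0.770 with an estimated correlation). No member of either list passed on its own. Rpl29 had 149 ± 46.2 CPM under saline and 227 ± 6.34 CPM under nicotine, and Ndufb7 had 59.0 ± 19.5 and 81.4 ± 1.14 CPM. Without saline library 2 the log2 fold change of Ndufb7 went from 0.46 to 0.21 and that of Rpl29 from 0.61 to 0.48. These are short transcripts, and the saline group held library 2 with its larger share of long ones: across 10859 genes, which are not independent replicates, the nicotine effect at 7 months had a Spearman correlation of -0.61 with transcript length.

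The oligodendrocyte and myelin list was lower, with 0 of 20 members above 0 (adjusted p = 2.2e-08, and adjusted p = 0.770 with an estimated correlation). Its member Aspa had 19.0 ± 2.80 CPM under saline and 10.5 ± 2.60 CPM under nicotine. No member passed over all genes. Cholesterol synthesis genes were lower too (3 of 20 members above 0; adjusted p = 0.00273, and adjusted p = 0.770 with an estimated correlation), a call that was lost without saline library 1 (adjusted p = 0.0584). Plaque-associated microglia genes were called higher by a narrow margin (22 of 30 members above 0; adjusted p = 0.0494, and adjusted p = 0.799 with an estimated correlation). That call was lost without nicotine library 1 (adjusted p = 0.154) or nicotine library 2 (0.132), and its direction turned without saline library 2 (0.262). The choroid plexus list had a median of 1.23 and was not called (adjusted p = 0.842), but it was called without nicotine library 1, in the other direction (3.9e-07), and without nicotine library 2 (7.5e-05).

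None of the genes followed in every comparison was called at 7 months, Arc and Fos included. App had log2 fold change -0.02 (SE 0.11), Gfap 0.00 (SE 0.20), Trem2 0.17 (SE 0.36) and Cst7 -0.22 (SE 0.53). The nicotinic receptor list was not called (adjusted p = 0.633). Chrna4 had -0.17 (SE 0.17) and Chrnb2 -0.05 (SE 0.10), while Chrna7, the subunit of homomeric alpha7 receptors, had 11.6 ± 9.99 CPM under saline and 5.59 ± 0.375 CPM under nicotine (log2 fold change -1.04, SE 0.53). Its saline mean was set by library 2. The signs of App, Gfap, Trem2, Cst7 and Chrnb2 turned with single libraries left out.

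Of the 41 lists, 12 were called at 7 months (5 higher, 7 lower), none with an estimated correlation. In all, 2 of 17596 genes passed at 7 months (1 higher, 1 lower; 1144 genes at an unadjusted p under 0.05), and DESeq2 called 81. Among the libraries left out in turn, edgeR called 0 genes without saline library 2 (1519 at an unadjusted p under 0.05), saline library 3 (1677) or nicotine library 1 (980), where Plin4 had adjusted p of 0.0655, 0.0565 and 0.0567, and 1 gene without nicotine library 2, where Egr2 had 0.232; without nicotine library 3 Egr2 had 0.262. Chosen after the data were seen, a fit without saline library 2 and nicotine library 1 called 1 gene, which was neither Plin4 nor Egr2. A fit without both 7-month libraries numbered 3, chosen after the data were seen as well, called 5 genes, of which 1 was among the 2, and Egr2 had adjusted p = 0.249.

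The second comparison asked the same at the later stage. In 18-month mice 8 of 18196 genes passed (4 higher, 4 lower; 1225 at an unadjusted p under 0.05), and they were not those of the 7-month comparison. Scg5, which codes for the neuroendocrine chaperone 7B2 and lies on chromosome 2 at 113776313 to 113829091, fell from 179 ± 9.05 to 99.5 ± 5.37 CPM (log2 fold change -0.84, SE 0.06, adjusted p = 0.000656). The DNA repair gene Tdg (chromosome 10, 82629814 to 82650799) rose from 8.12 ± 0.300 to 22.1 ± 5.78 CPM (log2 fold change 1.45, SE 0.17, adjusted p = 0.0289). Rpl26 (chromosome 11, 68901566 to 68904534) fell from 63.7 ± 3.33 to 24.8 ± 2.55 CPM, while Gm15772 (chromosome 5, 3236390 to 3236928) rose from 52.7 ± 1.36 to 101 ± 2.67 CPM. Their transcripts are 99.5% identical over 438 nt, so reads of this pair may be split between them, and their values are uncertain.

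The other genes that passed were mostly pseudogenes or predicted genes. Tmem181c-ps rose from 10.8 ± 1.27 to 45.1 ± 2.52 CPM (adjusted p = 6.2e-05), and its transcript is 99.6% identical to that of Tmem181b-ps over 759 nt. Gm5499 fell from 6.98 ± 0.275 to 1.49 ± 0.207 CPM, and its transcript is 99.4% identical to that of Tmx2 over 885 nt. LOC102637542 fell from 4.84 ± 1.25 to 0.931 ± 0.160 CPM. Trim12a rose from 0.0454 ± 0.0787 to 1.67 ± 0.0903 CPM; the saline group held 3 counts of it in all, so no fold is given. Nxph3 (adjusted p = 0.0572) and AA465934 (0.0592) did not pass. The Tdg transcript is 99.2% identical to that of Gm9855 over 1194 nt and 100% identical to that of Glt8d2 over 367 nt, and its values are uncertain as well.

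Glucocorticoid-response genes were higher at this age: 16 of 17 members lay above 0, none passed over all genes, and 12 were higher when adjusted over the list alone. The median log2 fold change was 0.33, with adjusted p = 9.8e-19 by camera and adjusted p = 0.327 with an estimated correlation. Plin4 had 10.6 ± 3.11 CPM under saline and 26.9 ± 4.72 CPM under nicotine (adjusted p = 0.0932). Tsc22d3, known as GILZ, had 56.3 ± 9.30 and 86.1 ± 6.68 CPM (adjusted p = 0.231), and the metallothionein Mt2 had 82.4 ± 2.30 and 103 ± 6.38 CPM (adjusted p = 0.164). Immediate early genes were not called as a list (11 of 30 above 0; adjusted p = 0.0763), with 2 lower when adjusted over the list alone. Without saline library 2 (adjusted p = 0.00203), saline library 3 (0.0322), nicotine library 1 (0.0114) or nicotine library 3 (0.0393) the list was called lower. Npas4 had 30.5 ± 8.14 and 18.0 ± 0.846 CPM (adjusted p = 0.351), and Fos 29.2 ± 9.55 and 18.0 ± 2.27 CPM (adjusted p = 0.575).

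Several other lists were called at 18 months. Dentate granule cell genes were higher (16 of 16 above 0, median 0.25; adjusted p = 3.9e-05, and adjusted p = 0.653 with an estimated correlation), with C1ql2 at 52.3 ± 4.43 and 70.6 ± 15.8 CPM. The call was lost without nicotine library 3 (adjusted p = 0.0703), where the log2 fold change of C1ql2 went from 0.43 to 0.26. Unfolded protein response genes were higher (19 of 21 above 0, median 0.09; adjusted p = 3.9e-05, and adjusted p = 0.327 with an estimated correlation), with the chaperone Hspa5 at 191 ± 4.27 and 221 ± 20.5 CPM. Cholesterol synthesis genes were lower (0 of 20 above 0, median -0.13; adjusted p = 8.5e-06, and adjusted p = 0.653 with an estimated correlation). Neurogenesis and proliferation genes were lower (2 of 13 above 0; adjusted p = 0.00372, and adjusted p = 0.327 with an estimated correlation), with Sox2 at 34.8 ± 4.43 and 25.4 ± 2.11 CPM. None of these members passed over all genes.

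Plaque-associated microglia genes were lower at 18 months (5 of 30 above 0, median -0.11; adjusted p = 0.000607, and adjusted p = 0.653 with an estimated correlation). None passed alone; Lgals3 had 2.16 ± 0.525 and 1.41 ± 0.132 CPM. Meningeal and fibroblast genes were higher (14 of 15 above 0, median 0.46; adjusted p = 1.8e-05, and adjusted p = 0.653 with an estimated correlation), with Lum at 1.95 ± 0.0690 and 3.02 ± 0.473 CPM. Without nicotine library 2 both calls were lost (adjusted p = 0.0628 each), and the number of lists called fell from 17 to 7. Choroid plexus genes were higher (12 of 12 above 0, median 1.85; adjusted p = 0.00312, and adjusted p = 0.715 with an estimated correlation), and Sostdc1 had 1.52 ± 1.11 and 8.82 ± 12.5 CPM. That call was lost without saline library 3 (adjusted p = 0.0626), and without nicotine library 1, which held the most Ttr, its direction turned (0.556). The nicotinic receptor list was not called (adjusted p = 0.653), nor were App (-0.05, SE 0.08), Chrna7 (-0.09, SE 0.08), Chrna4 (0.04, SE 0.10), Chrnb2 (-0.02, SE 0.06), Gfap (-0.14, SE 0.12), Trem2 (-0.13, SE 0.08), Cst7 (-0.13, SE 0.16) and Arc (-0.47, SE 0.18), all as log2 fold changes.

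The 18-month count moved from 8 to 5 without saline library 2, to 21 without saline library 3 and to 18 without nicotine library 2. Calls of LOC102637542, Trim12a and Tdg were each lost with 3 or more of the 6 libraries left out in turn, with adjusted p up to 0.0530, 0.137 and 0.154, and in a fit over all 12 libraries edgeR called 0 genes (505 at an unadjusted p under 0.05), while DESeq2 within the age called 57.

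The nicotine effect was also averaged over both ages, and 7 of 19171 genes passed (4 higher, 3 lower). Fits of all 12 libraries took 1 spread per gene for both ages, though the spread was unequal. The common dispersion, a measure of spread between libraries of a group, was 0.0417 in the 7-month fit and 0.00956 in the 18-month fit. Over all 12 libraries it was 0.0269, below the 7-month value and above the 18-month value. Plin4 had log2 fold change 2.18 (SE 0.16, adjusted p = 0.000156), Hif3a 1.55 (SE 0.21, adjusted p = 0.0314), Xdh 1.25 (SE 0.14, adjusted p = 0.00884) and Gjb6 0.54 (SE 0.08, adjusted p = 0.0496). Xdh codes for xanthine dehydrogenase, Hif3a for a hypoxia-inducible factor subunit and Gjb6 for the astrocytic gap junction protein connexin 30. The 3 genes that fell were the immediate early genes Egr2 (-1.88, SE 0.15, adjusted p = 0.000318), Fos (-1.20, SE 0.16, adjusted p = 0.0314) and Egr1 (-0.74, SE 0.10, adjusted p = 0.0314). Within each age the nicotine and saline libraries of these genes did not overlap, except for Egr1 at 18 months. Such separation was seen in 17.4% of all genes tested at 7 months and in 11.7% at 18 months. Npas4 (-0.86, adjusted p = 0.0542), Ezr (0.34, adjusted p = 0.0831) and Pnpla7 (0.46, adjusted p = 0.1) did not pass.

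**Figure D2:**
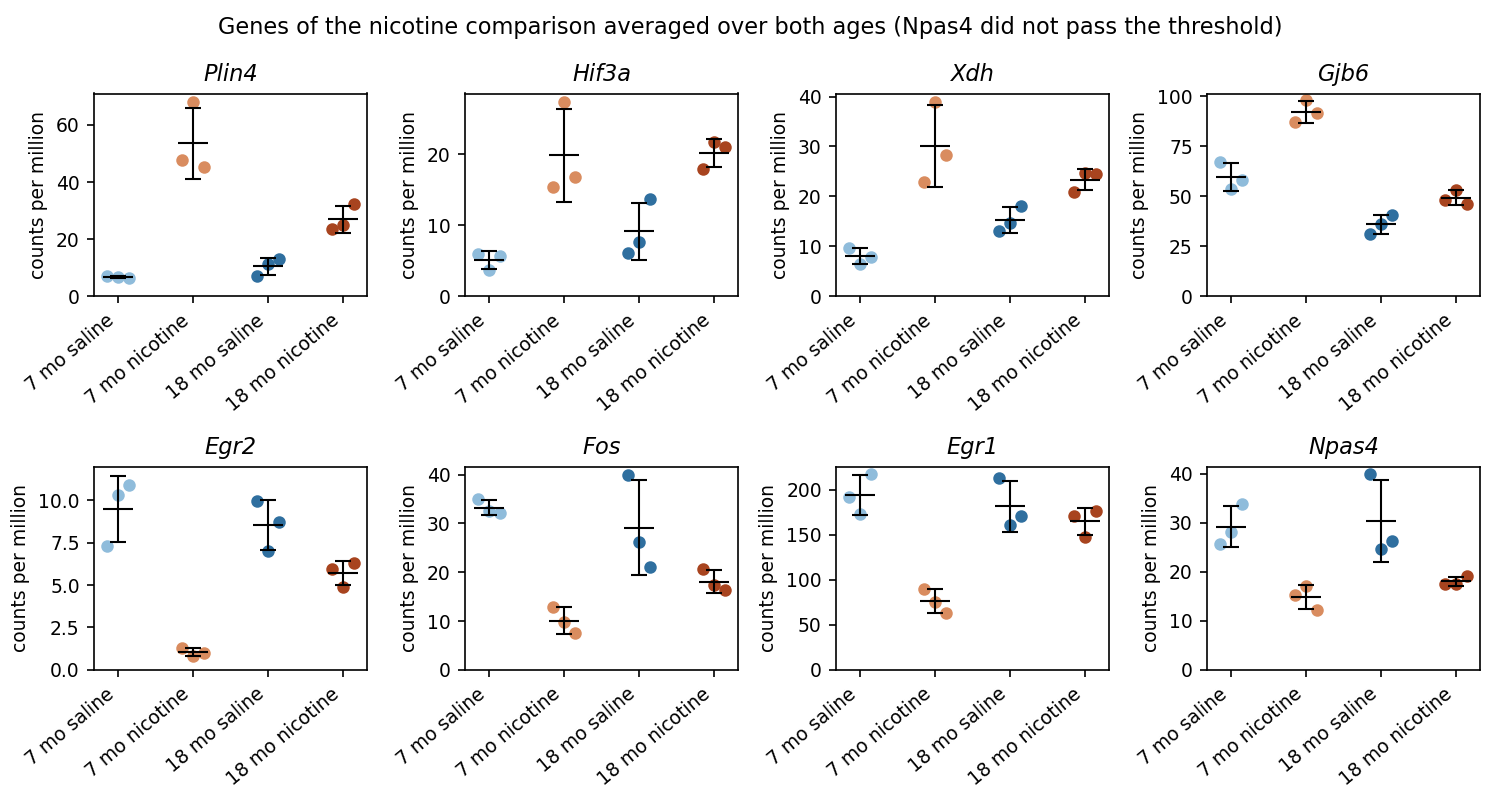
Each panel plots 1 gene, with the CPM of each library on the vertical axis and the 4 groups along the horizontal axis; points are libraries and bars are the mean and SD of 3. Plin4 and Xdh libraries of nicotine mice lie above those of saline mice at each age, and Egr2 and Fos libraries lie below.

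Over both ages the immediate early genes were lower (4 of 30 above 0; 3 passed over all genes, 15 lower and 1 higher adjusted over the list alone; adjusted p = 3.3e-15, and adjusted p = 0.119 with an estimated correlation). Glucocorticoid-response genes were higher (14 of 17 above 0; 2 passed, 9 higher and 2 lower adjusted over the list alone; adjusted p = 2.3e-09, and adjusted p = 0.283 with an estimated correlation), with Fkbp5 at 0.63 (SE 0.13, adjusted p = 0.205). Neurogenesis and proliferation genes were lower (3 of 14 above 0; adjusted p = 0.00105, and adjusted p = 0.135 with an estimated correlation); Igfbpl1 had -2.11 (SE 0.46) and Nes, the progenitor filament nestin, -0.61 (SE 0.13), and neither passed. Cholesterol synthesis genes (3 of 20 above 0; adjusted p = 1.2e-06, and adjusted p = 0.748 with an estimated correlation) and oligodendrocyte genes (0 of 19 above 0; adjusted p = 4.7e-07, and adjusted p = 0.748 with an estimated correlation) were lower too, without a passing member.

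With replicate number as a block edgeR called 3 genes for the averaged effect, all among the 7. DESeq2 called 80 genes for the averaged effect, among them all 7, and edgeR called 6, of which 5 were among the 7, without 7-month saline library 2 and the first nicotine library of each age, a choice made after the data were seen. Without both 7-month libraries numbered 3, also chosen then, edgeR called 7 genes, of which 2 were among the 7, Plin4 and Egr2; Xdh (adjusted p = 0.0523), Fos (0.0804), Hif3a (0.0836), Egr1 (0.0836) and Gjb6 (0.184) did not pass. Plin4 and Egr2 passed in every fit with 1 library left out; the count was 21 without 7-month saline library 2 and 2 to 10 without any other, falling to 4 without 7-month saline library 1, 7-month nicotine library 2 or 18-month saline library 1, to 3 without 7-month nicotine library 3, 18-month nicotine library 1 or 18-month nicotine library 2, and to 2 without 18-month saline library 2 or 18-month nicotine library 3.

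Whether the nicotine effect differed between the ages was tested directly. Egr2 was the gene that passed: its nicotine effect was 2.59 higher on the log2 scale at 18 months (SE 0.30, adjusted p = 0.0346), since it fell from 9.49 to 1.04 CPM at 7 months and was 8.55 and 5.70 CPM at 18 months. Egr1 (1.21, SE 0.20, adjusted p = 0.267), Timp1 (-2.50, SE 0.37, adjusted p = 0.133), Trib2 (0.85, SE 0.13, adjusted p = 0.133), Gem (1.73, SE 0.26, adjusted p = 0.133) and Plin4 (-1.63, SE 0.30, adjusted p = 0.394) did not. As lists, immediate early genes (26 of 30 above 0; 9 higher adjusted over the list alone; adjusted p = 2.3e-09, and adjusted p = 0.428 with an estimated correlation), circadian genes (12 of 17 above 0; adjusted p = 0.00493, and adjusted p = 0.428 with an estimated correlation) and dentate granule cell genes (16 of 16 above 0; adjusted p = 0.000579, and adjusted p = 0.870 with an estimated correlation) had a higher nicotine effect at 18 than at 7 months. Per2 had a difference of 0.91 (SE 0.17, adjusted p = 0.394). App, Chrna7, Chrna4, Chrnb2, Gfap, Trem2, Cst7, Arc and Fos did not pass.

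With replicate number as a block edgeR called 0 genes for this difference (1219 at an unadjusted p under 0.05). DESeq2 called 37 genes for this difference, 3 passed in edgeR without 7-month saline library 2, and Egr2 passed without 7-month saline library 1 (adjusted p = 0.0126) or library 2 (0.0360). Without any other single library its adjusted p lay between 0.0512 and 0.246 and edgeR called 0 genes, with 986 to 2685 at an unadjusted p under 0.05. Without both 7-month libraries numbered 3, a fit chosen after the data were seen, 3 genes passed and Egr2 did not (adjusted p = 0.150).

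**Figure D3:**
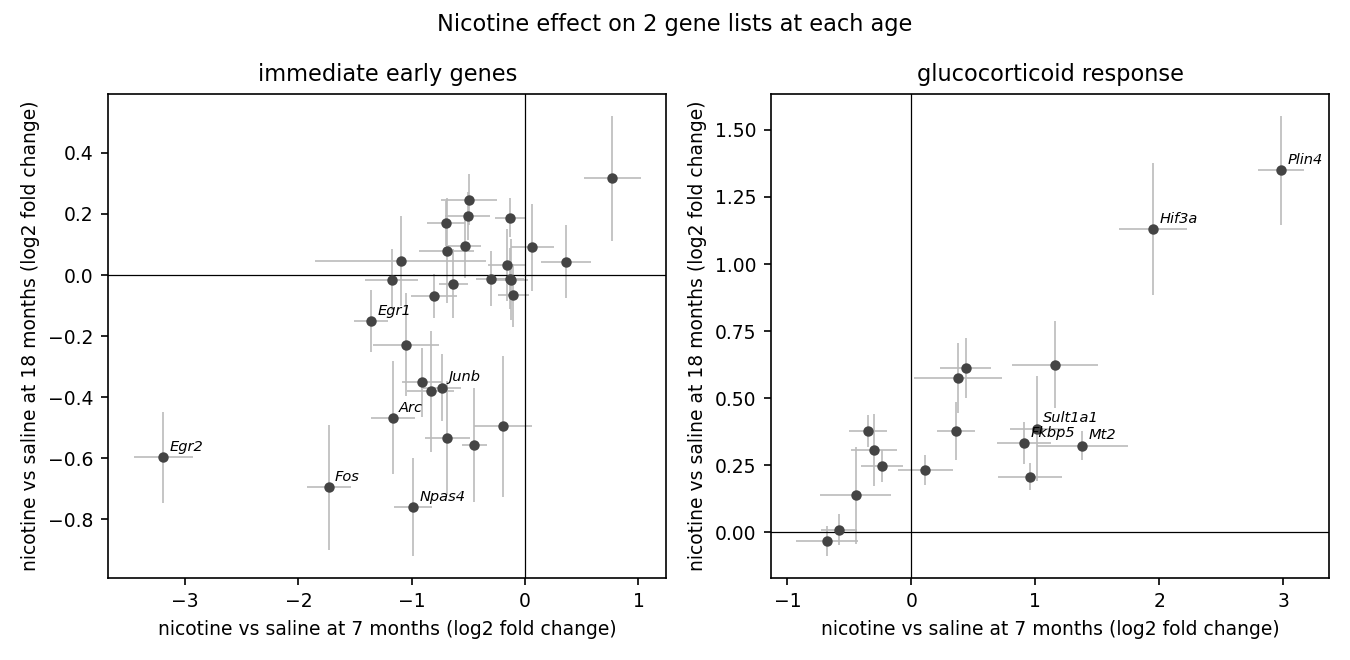
Each point is a gene of the immediate early list (left) or the glucocorticoid-response list (right), with the nicotine log2 fold change at 7 months on the horizontal axis, that at 18 months on the vertical axis, and bars of 1 SE. Most immediate early genes lie left of 0, and 16 of 17 glucocorticoid-response genes lie above 0 at 18 months.

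Across 16853 genes tested at both ages, which are not independent replicates, the nicotine effects at 7 and 18 months had a Pearson correlation of 0.068 and a Spearman correlation of -0.0187. Relabelling drug within each age 100 times gave a two-sided permutation p of 0.56 and 0.88. Of 154 genes with an unadjusted p under 0.05 at both ages, 87 (56.5%) moved in the same direction, with a permutation p of 0.82. A count added after the values were seen was the number of such genes itself: the median over relabellings was 34.5, and 2 of 100 relabellings, the real one included, gave 154 or more. The same-direction genes included Plin4, Xdh, Npas4, Hif3a, Gjb6, Egr2, Fkbp5 and Fos. The Pearson correlation was -0.0196 without 7-month nicotine library 1, 0.00859 without 7-month saline library 2, 0.0187 without 18-month nicotine library 1 and 0.123 without 7-month nicotine library 3. The share in the same direction was 45.5% without 7-month saline library 2 and 41.0% without 18-month nicotine library 2.

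Age was compared within each infusion, to describe how expression differed between the earlier and the later stage. Each age was deposited as its own table, so that age and any batch that goes with the table cannot be told apart. In saline mice 8844 of 19171 genes passed (4124 higher, 4720 lower at 18 months; 2574 by more than 2-fold), and in nicotine mice 11368 passed (5659 higher, 5709 lower; 4067 by more than 2-fold). Which direction held the majority turned with the scaling: of the genes called, 46.6% in saline mice and 49.8% in nicotine mice were higher with TMM factors, and 51.2% and 52.9% with RLE size factors. Of the 41 lists, 9 and 6 were called, none with an estimated correlation. Groups did not overlap in 49.7% and 68.9% of genes, where chance gives 10%. The count in saline mice was 11792 without 7-month saline library 2, and without 7-month saline library 1 it was 6251. Chosen after the data were seen, a fit without both 7-month libraries numbered 3 called 5761.

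Several genes of plaque-associated glia rose with age. The complement gene C4b (chromosome 17, 34728139 to 34743902) rose from 93.3 ± 15.9 to 371 ± 35.8 CPM in saline mice (log2 fold change 1.99, SE 0.14, adjusted p = 1.1e-05) and from 95.3 ± 7.43 to 347 ± 54.3 CPM in nicotine mice (1.86, SE 0.14, adjusted p = 8.8e-06). Gfap, the astrocyte filament protein (chromosome 11, 102887336 to 102897200), rose from 706 ± 207 to 1604 ± 197 CPM and from 713 ± 31.7 to 1469 ± 248 CPM (adjusted p = 0.000757 and 0.000659). The plaque microglia genes Gpnmb (1.74, SE 0.20, and 1.32, SE 0.20) and Lilrb4 (1.99, SE 0.27, and 1.99, SE 0.27) rose in both, and Clec7a rose from 2.08 ± 0.666 to 7.19 ± 1.42 CPM in saline mice. Cst7 rose by 1.16 (SE 0.44) and 1.27 (SE 0.44) on the log2 scale, and by 0.75 in saline mice without 7-month saline library 2; its calls were lost with other single libraries left out, with adjusted p up to 0.148 in saline mice and 0.0843 in nicotine mice. Trem2 did not pass, at 0.49 (SE 0.29) and 0.20 (SE 0.29), and in saline mice had 0.18 without 7-month saline library 2 and 0.84, which passed (adjusted p = 0.0431), without library 3.

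Of 30 plaque-associated microglia genes, 11 were higher and 2 lower in saline mice, and 7 higher and 4 lower in nicotine mice, where Apoe fell from 2669 ± 113 to 1518 ± 106 CPM. The list was called in saline mice (adjusted p = 0.0268, and adjusted p = 0.934 with an estimated correlation) and not in nicotine mice (adjusted p = 0.709). Without 7-month saline library 2 the saline call was lost (adjusted p = 0.742), as it was without 18-month saline library 1 (0.0546). Of 14 complement genes, 4 and 6 were higher and 2 and 2 lower, with C3ar1 at 1.55 (SE 0.24) and 1.49 (SE 0.24). Among 22 reactive astrocyte genes, 8 and 10 were higher and 2 and 3 lower, with Ggta1 at 1.49 (SE 0.16) and 1.25 (SE 0.15) and Osmr at 1.47 (SE 0.18) and 1.19 (SE 0.18). Antigen presentation genes numbered 3 higher and 2 lower of 20 in each infusion, with Nlrc5 higher (1.78, SE 0.28, and 1.82, SE 0.29) and Psmb10 lower (-0.80, SE 0.18, and -1.33, SE 0.19). Camera called none of the last 3 lists at either infusion (adjusted p from 0.119 to 0.882). Of all 19171 genes tested, 4124 were higher and 4720 lower in saline mice, and 5659 higher and 5709 lower in nicotine mice. The share of microglia genes called higher in nicotine mice lay below that of all genes. So did the share of antigen presentation genes called higher in each infusion.

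Genes of oxidative phosphorylation and of the ribosome fell together. These are short transcripts, and short transcripts fell as a class. Over 382 genes with transcripts under 1000 nt the median log2 fold change was -0.882 in saline mice and -1.13 in nicotine mice. All 66 measured oxidative phosphorylation genes were lower in each infusion (median log2 fold change -1.0 and -1.23; adjusted p = 1.5e-23 and 7.6e-23, and adjusted p = 0.916 and 0.969 with an estimated correlation), and 77 of 78 ribosomal protein genes were lower in each (median -1.01 and -1.30; adjusted p = 4.0e-23 and 5.6e-23, and adjusted p = 0.916 and 0.969 with an estimated correlation). Cox7c fell from 148 ± 35.7 to 52.0 ± 2.09 CPM in saline mice and from 176 ± 3.71 to 51.3 ± 2.40 CPM in nicotine mice, and Rpl38 from 142 ± 35.8 to 53.9 ± 1.27 CPM and from 172 ± 8.41 to 55.0 ± 2.75 CPM. Heat shock genes fell in 14 and 9 of 15 cases (adjusted p = 3.8e-05 and 0.00742, and adjusted p = 0.916 and 0.969 with an estimated correlation), with the chaperone Hspa8 at 1682 ± 323 and 827 ± 123 CPM in saline mice. Unfolded protein response genes fell in 12 and 13 of 21 cases (adjusted p = 0.000687 and 0.0292, and adjusted p = 0.916 and 0.969 with an estimated correlation), with Xbp1 at -0.93 (SE 0.10) and -0.64 (SE 0.10). In nicotine mice the last call was lost without 7-month saline library 2 (adjusted p = 0.0785) or 7-month nicotine library 1 (0.0543). Neuropeptide genes fell in 14 of 20 cases in nicotine mice (adjusted p = 0.00311, and adjusted p = 0.969 with an estimated correlation), with chromogranin A (Chga) at -1.0 (SE 0.12).

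Glutamate receptor and postsynaptic genes were higher at 18 months, 13 of 34 in saline mice and 21 of 34 in nicotine mice, against 2 lower in each (adjusted p = 0.00852 and 0.00742, and adjusted p = 0.916 and 0.969 with an estimated correlation). The NMDA receptor subunits Grin2b (chromosome 6, 135713221 to 136173615) and Grin2a rose most: Grin2b from 10.2 ± 2.04 to 469 ± 39.4 CPM and Grin2a from 12.4 ± 1.47 to 221 ± 7.80 CPM in nicotine mice. In saline mice Grin2b rose from 44.0 ± 53.1 to 465 ± 48.7 CPM; its 7-month mean was set by library 2, with 105 CPM against 10.2 and 16.7 in libraries 1 and 3. These lists moved with transcript length. In nicotine mice the median log2 fold change was -1.13 over 382 genes with transcripts under 1000 nt and 0.71 over 1881 genes with transcripts over 6000 nt, and across 10859 genes its Spearman correlation with length was 0.758.

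**Figure D4:**
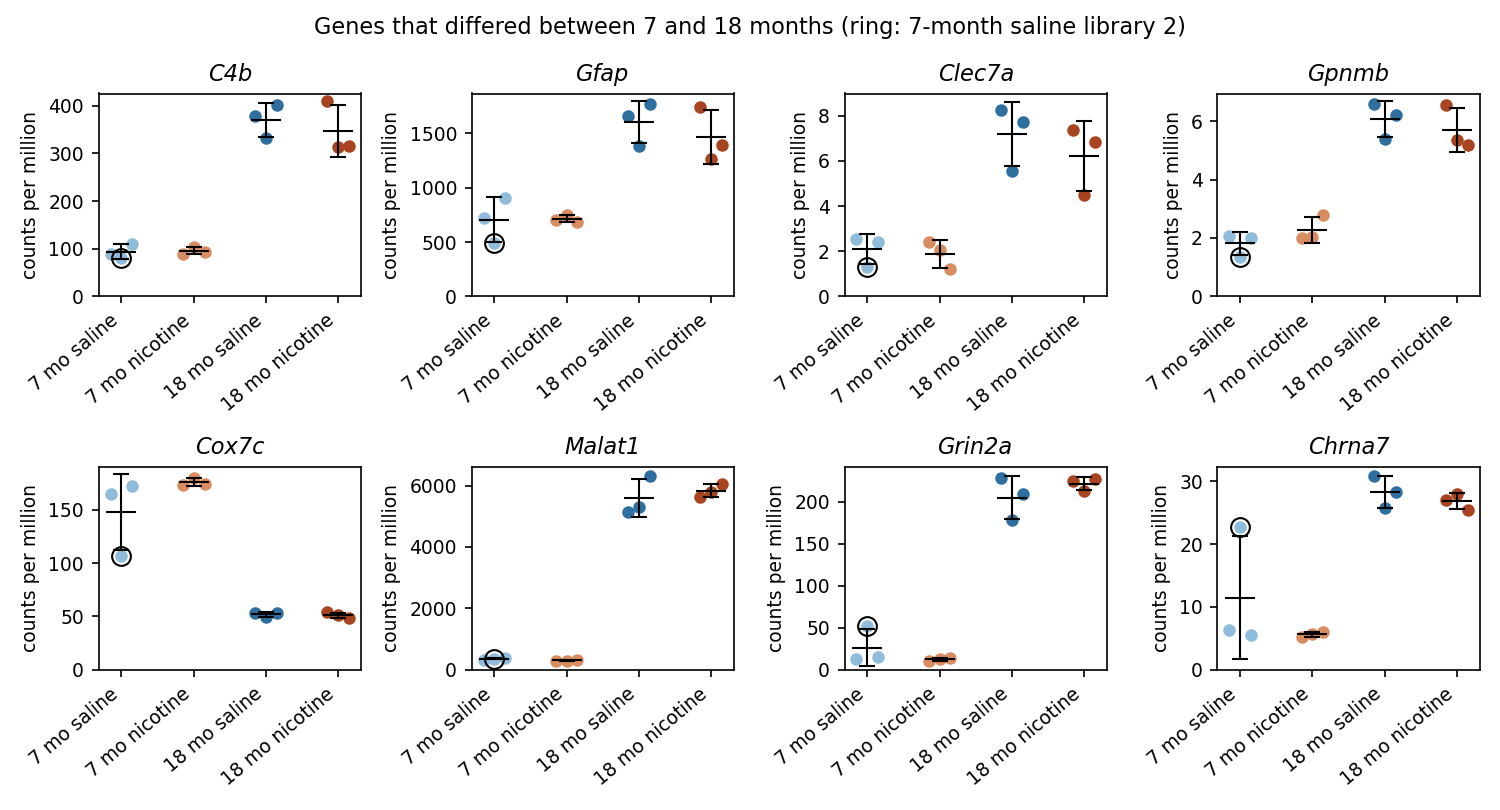
Each panel plots 1 gene, with CPM per library on the vertical axis and the 4 groups along the horizontal axis; points are libraries, bars are the mean and SD of 3, and a ring marks 7-month saline library 2. For Cox7c, Grin2a and Chrna7 that library lies on the 18-month side of its group; for C4b, Gfap, Clec7a, Gpnmb and Malat1 it lies among or below the 7-month libraries.

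Among the largest rises, Malat1 went from 361 ± 23.8 to 5589 ± 624 CPM and the transcription factor gene Zbtb20 (chromosome 16, 42875689 to 43634392) from 4.33 ± 1.78 to 113 ± 5.38 CPM in saline mice; in nicotine mice Zbtb20 went from 3.67 ± 0.371 to 117 ± 10.4 CPM. Cdr1, Kcng3, Kcna3 and Srrm4os were among the 10 largest rises in both infusions, with Muc6 and TrnL2 in saline mice and Dok6 and Lnpep in nicotine mice. Rn18s-rs5, Rn7sk and Lars2 also held more CPM in every 18-month library than in any 7-month library. The 7-month libraries numbered 3 had raised values of these RNAs, with Malat1 within the range of the other 7-month libraries. The design cannot tell such rises from a batch that goes with the table. The largest fall in both was Bc1, a dendritic noncoding RNA, from 85.5 ± 92.5 to 1.71 ± 0.246 CPM in saline mice, where 7-month library 2 had 192 CPM and libraries 1 and 3 had 37.0 and 27.4, and from 34.7 ± 8.27 to 1.40 ± 0.429 CPM in nicotine mice. Egfl8 followed, at -2.44 (SE 0.19) and -2.81 (SE 0.20). Ctxn3, Slc6a13, Gpx8, Hspb1, Ptgds, Slc22a6, Cbln1 and Prg4 made up the 10 in saline mice, and Crybb1, Erdr1, Rpl26, Insl5, Tmem256, Mt3, Nrtn and Pdzd9 those in nicotine mice.

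App rose by 0.39 (SE 0.10, adjusted p = 0.0064) in saline mice and 0.36 (SE 0.10, adjusted p = 0.00635) in nicotine mice on the log2 scale, and with offsets for transcript length and GC content, chosen after the data were seen, its values were -0.14 and -0.44. The labels do not say whether transgene reads are counted under App. In saline mice 9 of 31 amyloid and tau genes were higher and 6 lower (adjusted p = 0.981), with Lrp1 higher (0.96, SE 0.14) and the gamma-secretase subunit gene Psenen lower (-1.17, SE 0.19). Chrna7 rose from 11.5 ± 9.72 to 28.3 ± 2.54 CPM in saline mice, where 7-month library 2 had 22.7 CPM and libraries 1 and 3 had 6.27 and 5.49, and from 5.67 ± 0.367 to 26.8 ± 1.28 CPM in nicotine mice. The saline call was lost without 7-month saline library 1 (adjusted p = 0.0744) or 3 (0.0560) or 18-month saline library 1 (0.0539). The nicotinic receptor list was not called in either (adjusted p = 0.981 and 0.980). Lynx1, a modulator of these receptors, fell in nicotine mice (-0.63, SE 0.13). Chrna4, Chrnb2 and Arc passed in neither, and Fos rose in nicotine mice by 0.84 (SE 0.23, adjusted p = 0.00740).

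Among 16923 genes with a transcript length, a choice made after the data were seen, 7467 passed in saline mice and 9903 in nicotine mice. With offsets for transcript length and GC content the same genes gave 5612 and 7629, and 4193 and 5584 passed in the same direction in both fits. With the offsets the glutamate list was not called (adjusted p = 0.504 and 0.442), while C4b (1.77 and 1.62), Gfap (1.47 and 1.46) and Gpnmb (1.75 and 1.30) stayed higher at 18 months, as log2 fold changes in saline and nicotine mice.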

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

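Tests chosen after the results were seen are those of the library profile, a mislabelled sample, age itself, 1 saline library with another profile, tissue carried over in 1 nicotine library, the length trend at 7 months, swaps within replicate numbers, and reads shared between paralogs, together with the length and GC offsets. The length trend test of glial genes, the inherited-difference test and the splits were set before the values they measure were seen. The spread percentile and the share of genes of like expression given beside the inherited-difference test were not part of its rule.

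The test of the difference between ages singled out Egr2, whose nicotine effect was 2.59 higher on the log2 scale at 18 months. In the same test by camera 9 lists differed, none with an estimated correlation (smallest adjusted p = 0.428). The median difference was 0.50 for immediate early genes, 0.23 for circadian genes, 0.43 for dentate granule cell genes and 1.25 for meningeal and fibroblast genes, a list set for other tissue that a dissection could hold. It was -0.23 for plaque-associated microglia genes, -0.26 for neuropeptides, -0.15 for lysosome genes, -0.23 for oxidative phosphorylation genes and -0.24 for ribosomal protein genes. Of 100 splits, 26 gave as many genes as the 1 called, so chance cannot be excluded for that count. The highest gave 7, but it kept the true groups and swapped drug at 18 months, so it measured the averaged effect. Splits that keep the true groups at 1 age hold drug effects too, so this test cannot measure chance for the difference. For the averaged effect 1 of 100 splits drawn, the real one, gave 7 genes and the highest other gave 6. In the fit without a replicate block this share lies under 0.05, by a narrow margin and without adjustment over the 6 comparisons. It argues against chance without excluding it. With the block 3 genes were called, and 4 of 32 swaps of drug within same-number libraries gave as many (highest other 3), so in that fit chance is not excluded. For nicotine at 7 months 3 of 10 splits gave 2 genes or more (highest other 4), for nicotine at 18 months 1 of 10 (real 8, highest other 6), for age in saline mice 1 of 10 (8844 and 0) and for age in nicotine mice 1 of 10 (11368 and 1); 10 splits are too few for a share under 0.05. Groups of 3 libraries were not tested for outliers.

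Age differences followed transcript length, and 7-month saline library 2 had part of the same profile. Its departure from the rest of its group correlated with the age difference in nicotine mice, which has no library in common with it, at r = 0.795 across 11022 genes with a mean log2 CPM over 3 and at r = 0.519 across all 19171 tested, so the profile may arise in library preparation or RNA handling and need not follow age. A mislabelled 18-month library is argued against: it lay nearer to the 18-month mean for 74.8% of 131 genes with large age differences (exact 95% interval 66.5% to 82.0%), where each 18-month library did so for 97.7% or more, and its Malat1 was at the 7-month level. It lay far from its labelled group as well, since 7-month saline libraries 1 and 3 did so for 0.763% and 1.53%. The 131 genes were picked by the age difference in nicotine mice, which favours a high share in the 18-month nicotine libraries. The 131 genes are not independent replicates, so the interval does not measure spread between libraries or animals. The argument rests on the 18-month libraries and on Malat1, and the bound for this test was set after the value was seen. Age itself stays open, since 1 library of the 7-month mice lay nearer to the 18-month libraries, and the table, its batch and age cannot be told apart. A length trend is argued against as the whole cause of the glial genes called higher: of 46 gene and comparison pairs of the complement, plaque microglia and reactive astrocyte lists called higher, 97.8% stayed higher past the threshold with length and GC offsets, with a median log2 fold change of 1.19 before and 1.34 after, while 5 of the 15 pairs of these lists called lower stayed lower. Over 16923 genes with a transcript length, 56.2% of calls in saline mice and 56.4% in nicotine mice stayed past the threshold in the same direction.

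At 7 months immediate early genes were lower and glucocorticoid-response genes higher under nicotine. Over all 47 tested members of both lists the median change in the direction of the pattern was 0.53 on the log2 scale, with 38 in that direction; it was 0.480 without saline library 2, 0.555 without nicotine library 1, which held choroid plexus and pituitary transcripts, and 0.595 with length and GC offsets. Camera called both lists in each of these fits (adjusted p = 2.0e-19 and 0.00811, 1.7e-14 and 0.000227, 2.6e-22 and 0.00396), which argues against each as the whole cause, within the limit that neither list was called with an estimated correlation. Part of the change may still come from saline library 2, since without it the list medians went from -0.66 to -0.52 and from 0.38 to 0.26. Nicotine itself, a stress response to the infusion, or a difference in handling or hour of dissection between groups may each give such a pattern, and the design tests none of them against the others.

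The 8 genes called at 18 months were mostly pseudogenes, predicted genes or genes with close relatives. Shared reads stay open for most of them: of 7 that could be searched, 5 had a similar transcript elsewhere, against 17.5% of 200 genes of like expression. The rule of this test counted 3 of the 8 against shared reads: Scg5 and Trim12a, with no such transcript, and Tmem181c-ps, whose partners rose too. Rows that share reads can also rise together, so shared reads are argued against for Scg5 and Trim12a and stay open for Tmem181c-ps. For Rpl26 and Gm15772 they may be the cause: their summed CPM were 117 under saline and 125 under nicotine, a log2 ratio of 0.104; Gm9855 moved against Tdg (-1.35, unadjusted p = 0.057) while the other partner of Tdg, Glt8d2, rose too (0.37, 0.00443), and Gm5499 is too weak beside Tmx2 (133 and 131 CPM summed) for a shift to be seen. For inherited differences between mice, 3 of the 8 genes had a library at least 4 times above another of its own group. That is fewer than the bound set in advance, which by that rule counts against them. Outside the rule, 7 of 8 lay at or above the 95th percentile of spread at 7 months, and 4.88% of genes of like expression reach 4 times. These measures were not set in advance and do not replace the bound, so inherited differences stay open. An effect of nicotine on these genes is untested against them, and 0 of the 7 that could be tested at 7 months changed in the same direction at an unadjusted p under 0.05 there by edgeR.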

How the results depend on the processing

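The length and GC offsets, the fits of genes with a transcript length and those without libraries in doubt were chosen after the data were seen. RLE size factors kept every count of genes within 1.5 times and moved the median age effect from -0.03 to 0.01 on the log2 scale in both infusions. The cause of the changes below was not tested, except that fits with fewer libraries have fewer degrees of freedom. Fits of all 12 libraries also took 1 spread per gene for both ages, though the common dispersion was 0.0417 at 7 months and 0.00956 at 18 months.

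Counts of genes for nicotine at 7 months (2) were 6 with no filter on low counts, 81 by DESeq2, 1 with a replicate block, 9 with 12 libraries in 1 fit, 0 without both first 7-month libraries (edgeR; 899 at an unadjusted p under 0.05), 1 without saline library 2 and nicotine library 1, 5 without both 7-month libraries numbered 3, and 0 to 2 leaving 1 library out. At 18 months (8) they were 35, 57, 9, 0 with 12 libraries in 1 fit (edgeR; 505 at an unadjusted p under 0.05), and 5 to 21 leaving 1 out. For the average (7) they were 15 with no filter, 80 by DESeq2, 3 with a block, 12 with length and GC offsets and 2 to 21 leaving 1 out. For the difference (1) they were 37 by DESeq2, 0 with a block (edgeR; 1219 at an unadjusted p under 0.05), 2 without both first 7-month libraries, 3 without both numbered 3 and 0 to 3 leaving 1 out. For age in saline mice (8844) they were 5852 without both first 7-month libraries, 5761 without both numbered 3, 5612 with offsets (7467 for the same genes without), 8511 with a block and 6251 to 11792 leaving 1 out; in nicotine mice (11368), 7629 with offsets (9903 for the same genes without), 11017 with a block and 10137 to 12688 leaving 1 out.

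With an estimated correlation 0 lists were called in each of the 6 comparisons; fry called 1 at 7 months, 0 at 18 months, 1 for the average, 0 for the difference, 13 for age in saline mice and 16 in nicotine mice. The number at 7 months (12) was 19 without both libraries numbered 3, at 18 months (17) it was 7 to 20 leaving 1 library out, for the average (9) 18 without libraries in doubt, and for age in saline mice (9) 14 with offsets.

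Choroid plexus genes at 7 months turned to lower without both first libraries (adjusted p = 3.1e-12) and without saline library 2 and nicotine library 1 (9.3e-05), with 3.9e-07 to 0.970 leaving 1 out; at 18 months the range was 4.7e-10 to 0.556. Plaque-associated microglia genes at 7 months turned to lower without saline library 2 and nicotine library 1 (0.0610), with 0.00271 to 0.262 leaving 1 out; over genes with a transcript length alone they had 0.0524, and unfolded protein response genes with age in nicotine mice 0.0505. With length and GC offsets App had log2 fold changes with age of -0.14 and -0.44 in saline and nicotine mice, Chrnb2 -0.26 and -0.34, and in nicotine mice Cfp had 0.20 and Nmb 0.060.

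The correlation of nicotine effects between ages was -0.00628 over genes with a mean log2 CPM of at least 3, 0.0258 with a block and -0.0196 to 0.123 leaving 1 library out. The rank correlation ranged from -0.0716 to 0.0465 and the same-direction share from 41.0% to 72.6%. Depth limits weakly expressed genes most, and at 7 months 2-fold changes were recovered in 38% of simulated cases.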

Other observations

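Ependymal genes were lower under nicotine averaged over both ages (1 of 12 above 0, median log2 fold change -0.32; adjusted p = 0.0053, and adjusted p = 0.748 with an estimated correlation). None passed alone, and the cilia genes Ak7 and Hydin had log2 fold changes of -0.67 (SE 0.25) and -0.75 (SE 0.32). Part of this may come from 7-month saline library 2, with 2.92 CPM of Hydin against 0.900 and 0.923 in saline libraries 1 and 3. Its Ak7 was 6.35 CPM against 3.47 and 3.80, while its Tmem212, 2.53 CPM against 3.10 and 2.25, was not the highest. Ribosomal protein genes (77 of 78 above 0, median 0.15; adjusted p = 5.1e-14, and adjusted p = 0.748 with an estimated correlation) and oxidative phosphorylation genes (66 of 66 above 0, median 0.13; adjusted p = 6.0e-12, and adjusted p = 0.749 with an estimated correlation) were higher in the same comparison. These are short transcripts, and at 7 months, where the saline group held library 2 with its larger share of long ones, the nicotine effect had a Spearman correlation of -0.61 with transcript length across 10859 genes, against 0.0931 at 18 months. The nicotine effect on both lists was lower at 18 months, by a median of 0.24 and 0.23, in calls by camera that were not made with an estimated correlation (smallest adjusted p over all lists 0.428). Genes encoded by the mitochondrial genome were higher (9 of 13 above 0; adjusted p = 0.0154, and adjusted p = 0.748 with an estimated correlation). At 18 months lysosome genes were lower under nicotine (1 of 26 above 0, median -0.05; adjusted p = 0.00135, and adjusted p = 0.327 with an estimated correlation).

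In saline mice meningeal and fibroblast genes fell with age in 12 of 15 cases (median -1.32; adjusted p = 0.0019, and adjusted p = 0.916 with an estimated correlation), with Lum at -1.32 (SE 0.22) and Ogn at -1.57 (SE 0.35). Oligodendrocyte and myelin genes fell in 9 of 19 cases (adjusted p = 0.00852, and adjusted p = 0.934 with an estimated correlation), with Mal at -0.85 (SE 0.24). Neuropeptide genes fell in 8 of 20 cases (adjusted p = 0.0268, and adjusted p = 0.916 with an estimated correlation), with Penk, the proenkephalin gene, at -1.19 (SE 0.24) and Nts, the neurotensin gene, at -1.56 (SE 0.36). The meningeal and fibroblast list was set for other tissue that a dissection could hold, and it was not among the 6 lists called in nicotine mice. Its member Aldh1a2 had 11.5, 6.28 and 2.92 CPM in 7-month saline libraries 1, 2 and 3, while Lum had 4.90, 4.70 and 4.83.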
